A study of Mus musculus with 23 samples.

How the data were processed

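Affymetrix arrays measured the RNA of gastrocnemius muscle in 9 groups: control, emerin KO (knockout) and lamin A/C KO mice on days 0, 3 and 4, with 2 or 3 arrays per group and 23 in all, grouped by title and description. The title gave the genotype of control day 4 replicate 2, whose description leaves it out. The authors deposited 1 value per probe set and array, a MAS5 signal (intensity, linear scale; the MAS5 version is not given in the sources used here), with every array scaled to 1 trimmed mean: the mean without the lowest and highest 2% was 150.04 to 150.06 on each array. No 2 arrays held identical values.

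Each array was rescaled to a trimmed mean of 500 (factor 3.332) and log2(signal + 32) was taken. Of 22690 probe sets, 64 Affymetrix controls, 691 with several gene symbols and 1555 with no listed gene were left out of the gene tests, and 20380 had 1 symbol. The brightest probe set stood for each of 12393 genes (4956 had several), and 11164 genes with a signal of at least 100 on at least 2 arrays were tested. The limit and the number of arrays set the precision of the values. The 3'/5' ratio of the Gapdh control probe sets was read as a measure of RNA quality. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

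Linear models with limma 3.58.1 (R 4.3.3, with the data.table package, version 1.17.8, trend=TRUE) were fitted to all 9 groups together, which then share 1 estimate of the spread, with 14 residual degrees of freedom. There were 20 comparisons: changes between days within a genotype, genotype differences on each day and over the 3 days, and interactions. Every p in the text is from limma or from camera (limma), adjusted by Benjamini-Hochberg within a comparison, and past the threshold means an adjusted p under 0.05. Camera with a preset inter-gene correlation of 0.01 was run on 27 of 28 gene lists with at least 5 measured genes; where the call ended with a correlation estimated from the data, that adjusted p is given too. The lists, written before the data were examined, are nuclear envelope and lamina, Rb/E2F pathway, myogenic regulators, regenerating myofiber, mature fast contractile, slow fiber, oxidative phosphorylation, glycolysis and glycogen, DNA replication, mitosis, macrophage, neutrophil, lymphocyte, chemokines and cytokines, interferon response, extracellular matrix and fibroblast, adipocyte, endothelial, erythroid, Schwann cell and nerve, denervation and atrophy, amino acid and ER stress response, p53 targets, immediate early and MAPK, TGF-beta and Wnt targets, circadian clock, cytosolic ribosome and sex-linked genes. Of 751 list symbols, 663 had a probe set. Lists share members. The symbol lookup was corrected after the list results had been seen: it had matched 668 symbols, 5 of them to wrong genes. The correction changed 2 of 540 list calls, glycolysis and glycogen in emerin KO minus control on day 4 (adjusted p 0.10 before, 0.050 after, 0.48 with an estimated correlation) and cytosolic ribosome from day 3 to day 4 in control (0.065 before, 0.041 after, 0.45 with an estimated correlation), and turned 0 directions among called lists.

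The groups, the comparisons, the tests, the alternatives and the rule for naming genes were set before the data were examined. The rule names, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap between the compared groups (over the 3 days: differences of the same sign on each day; interactions: no such condition), all genes where 10 or fewer passed, Emd and Lmna in every comparison of genotypes, and up to 4 members of each described list with the largest change, or up to 2 with the smallest p where none passed; some members were left out where another probe set had the opposite sign (Ccl9, Mbp, Myl4, Rpa2, Rrm2 and Trem2, each in 1 or 2 comparisons). Unnamed cDNAs and gene models are counted only. Genes read by a probe set whose ID ends in _x_at or _s_at may share signal with relatives: of the genes named in the report these are Bgn, Casq2, Ccn3, Cdk4, Cnp, Cotl1, Fbl, Fermt3, Gga1, H2-Aa, Hspa1b, Incenp, Laptm5, Mcm2, Mcm7, Ms4a4c, Myl3, Nasp, Phkg1, Rasd2, Rps9, Rrm2, S100a8, Sesn1, Tnnt2, Trmt1 and Usp38.

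On simulated data with changed genes of known size, the fit recovered 58.2% of 2-fold and 97.0% of 4-fold changes for emerin KO minus control on day 3, 46.3% and 89.4% for lamin A/C KO minus control on day 0, 92.5% and 100% for lamin A/C KO minus control over the 3 days, and 26.9% and 84.8% for the lamin A/C KO interaction, with 5 to 7 false calls in each. The alternatives were quantile normalization, median scaling, the values as deposited (pseudocount 9.6, minimum 30), pseudocounts of 1 and 100, no filter, the mean of all probe sets of a gene, no intensity trend, the replicate number as a block, only the compared groups in the fit, leaving out each array in turn, and splitting the controls. The Gapdh ratio as a covariate and leaving out the 5 arrays with a ratio over 2 were added after the data were seen.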

Results

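Gene expression was measured on 23 arrays of gastrocnemius muscle from control mice, mice lacking emerin and mice lacking lamin A/C, the nuclear envelope proteins whose genes are mutated in Emery-Dreifuss muscular dystrophy. Muscle was taken on day 0 and on day 3 and day 4 after an injection that set off degeneration and regeneration. There were 2 control arrays on each day, 2 emerin KO (knockout) arrays on day 0 and 3 on each later day, and 3 lamin A/C KO arrays on each day. After rescaling, 11164 genes were bright enough on at least 2 arrays to be tested, and the number of arrays limits the precision of each value. The labels do not say that the arrays of a group come from separate animals, so the p-values measure the spread between these samples. The titles name the 6 control arrays as controls of the lamin A line, so a difference between emerin KO and control can include a difference in background between the lines. The day 0 lamin A/C KO arrays are described as taken 0 days after injection, while those of the other day 0 groups are described as not injected.

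The first component of the variation over all genes, with 56.6% of the variance, parted the day 0 arrays from the injected ones, and the second held 10.8%. RNA quality, read from the Gapdh 3'/5' signal ratio, was not even over the groups. The ratio lay between 3.62 and 6.09 on the 3 emerin KO day 3 arrays (mean 4.83, SD 1.23, n = 3) and was 2.89, 1.40 and 5.30 on the 3 emerin KO day 4 arrays (mean 3.20, SD 1.97, n = 3). On the 15 control and lamin A/C KO arrays it lay between 0.822 and 1.64, and on the emerin KO day 0 arrays it was 0.914 and 1.34. Within lamin A/C KO it was 1.21 to 1.64 on day 3 and 0.822 to 0.888 on day 4.

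**Figure D1:**
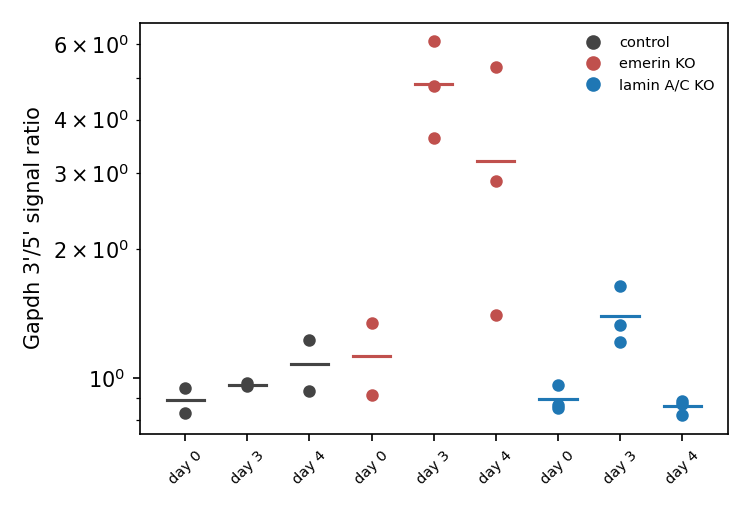
Gapdh 3'/5' signal ratio (log axis) of each of the 23 arrays by genotype and day, with a bar at each group mean. The 3 emerin KO day 3 arrays and 2 of emerin KO day 4 lie above 2.

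The targeted genes came first. The brightest Lmna probe set (of the transcript of lamins A and C) gave a mean signal of 77.8, 61.1 and 70.8 in lamin A/C KO on days 0, 3 and 4, against 890, 3992 and 3744 in control. The lamin A/C KO means lie under the minimum signal of 100, so Lmna is given only as at least 8.90-fold, 39.9-fold and 37.4-fold lower, from that minimum (adjusted p = 4.9e-09, 5.8e-14 and 1.4e-13). The next brightest Lmna probe set read 606, 993 and 686 in lamin A/C KO against 638, 2310 and 2014 in control. The 2 dimmer Lmna probe sets were not low in lamin A/C KO after injury: an _x_at set, which may share signal with relatives, read 461 and 274 on days 3 and 4 against 195 and 216 in control, and the dimmest read 390 and 247 against 21.0 and 39.7. Emd, which encodes emerin, gave 418, 262 and 207 in emerin KO on days 0, 3 and 4, against 678, 766 and 692 in control, and its signal on each of the 8 emerin KO arrays lay under that on each of the other 15. The difference did not pass on day 0 (-0.65 ± 0.30, adjusted p = 0.27) and passed on day 3 (-1.57 ± 0.27, adjusted p = 4.7e-04) and on day 4 (-1.61 ± 0.27, adjusted p = 0.0017). Emd did not differ past the threshold between lamin A/C KO and control, with 0.19 ± 0.27, 0.05 ± 0.27 and 0.04 ± 0.27 on the 3 days (adjusted p = 0.90, 0.98 and 1.0), nor did Lmna between emerin KO and control, with -0.37 ± 0.22, 0.14 ± 0.20 and 0.17 ± 0.20 (adjusted p = 0.43, 0.71 and 0.68). Here and throughout, a value after a gene is its log2 difference with its standard error (SE).

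**Figure D2:**
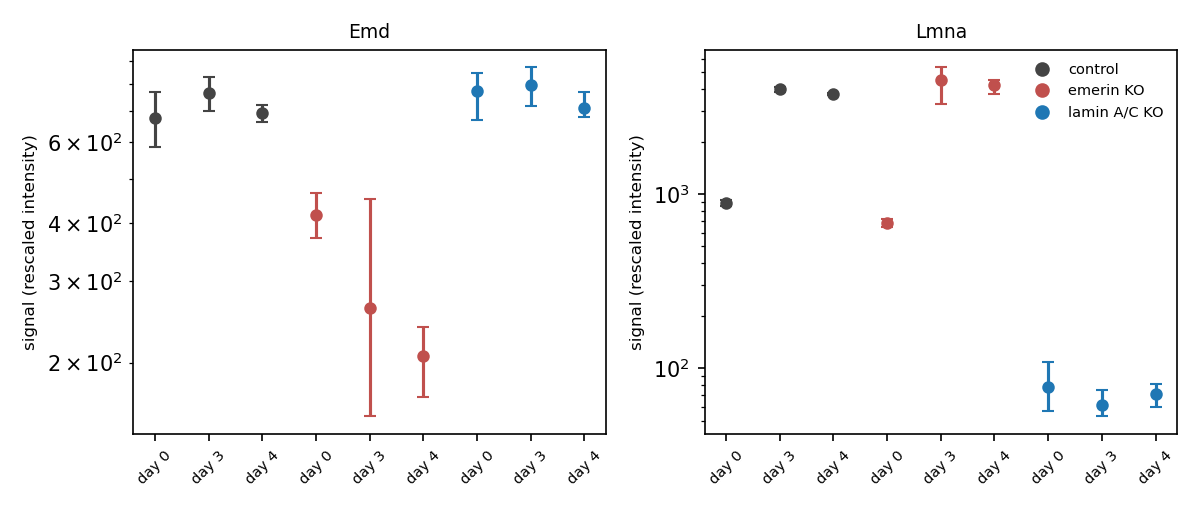
Mean signal (rescaled intensity, log axis) of the Emd probe set and of the brightest Lmna probe set in each genotype and day, with bars from the lowest to the highest array of the group (n = 2 or 3). Emd is at 418, 262 and 207 in emerin KO and Lmna at 77.8, 61.1 and 70.8 in lamin A/C KO.

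The change from day 0 to day 3 in control muscle gives the normal response to the injury. On day 3 the mature contractile and energy-producing program was low, and cycling, macrophage and embryonic muscle genes were high. The largest rises were in Chrng (5.0 ± 0.33), Gpnmb (4.84 ± 0.34), Tnnt2 (4.76 ± 0.23), Lgals3 (4.57 ± 0.26), S100a8 (4.53 ± 0.52), Mpeg1 (4.36 ± 0.43), Arg1 (4.36 ± 0.43), Myh3 (4.35 ± 0.32), Fcer1g (4.32 ± 0.41) and Fads3 (4.16 ± 0.36). Of these, Chrng is the fetal subunit of the acetylcholine receptor, Tnnt2 and Myh3 are embryonic or fetal muscle isoforms, Gpnmb, Lgals3, Mpeg1 and Fcer1g are macrophage genes and S100a8 is a neutrophil gene. The largest falls were in Myl3 (-6.01 ± 0.31), Myl2 (-5.81 ± 0.43), Rpl3l (-4.83 ± 0.34), Myh7 (-4.72 ± 0.27), Myh2 (-4.31 ± 0.86), Phkg1 (-4.18 ± 0.33), Cox7a1 (-4.09 ± 0.27), Mlf1 (-4.03 ± 0.35) and Asb10 (-3.89 ± 0.43), and in 1 cDNA symbol, among them the slow myosin chains Myl3, Myl2 and Myh7, the phosphorylase kinase subunit Phkg1 and the respiratory subunit Cox7a1. By limma, 2244 genes rose and 1580 fell of 11164 tested. Here and in the comparisons of 2 groups below, the arrays of the groups do not overlap for any gene given as a largest rise or fall. All 58 genes named with a call here kept it with any array left out.

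Of the 27 mature fast contractile genes measured, 0 rose, 27 fell and 0 did not pass (27 adjusted over the list alone, camera adjusted p = 5.7e-20). Called members include Ldb3 (-3.59 ± 0.28) and Tcap (-3.39 ± 0.30). Of the 13 slow fiber genes measured, 3 rose, 9 fell and 1 did not pass (3 up and 9 down adjusted over the list alone, camera adjusted p = 5.2e-05, adjusted p = 0.084 with an estimated correlation). An example is Mb (-3.06 ± 0.48). Of the 52 oxidative phosphorylation genes measured, 0 rose, 51 fell and 1 did not pass (51 adjusted over the list alone, camera adjusted p = 4.9e-33). Examples are Cox8b (-3.44 ± 0.23) and Cox6a2 (-2.94 ± 0.29). Of the 22 glycolysis and glycogen genes measured, 2 rose, 19 fell and 1 did not pass (2 up and 19 down adjusted over the list alone, camera adjusted p = 1.4e-13). Called members include Slc2a4 (-3.17 ± 0.19) and Phkb (-3.17 ± 0.27). Of the 23 regenerating myofiber genes measured, 15 rose, 3 fell and 5 did not pass (15 up and 3 down adjusted over the list alone, camera adjusted p = 2.1e-08). An example is Myl4 (3.83 ± 0.23). Of the 20 denervation and atrophy genes measured, 11 rose, 3 fell and 6 did not pass (11 up and 4 down adjusted over the list alone, camera adjusted p = 0.0020, adjusted p = 0.084 with an estimated correlation). Examples are Runx1 (4.07 ± 0.35) and Cdkn1a (3.26 ± 0.28). Of the 28 myogenic regulators measured, 10 rose, 3 fell and 15 did not pass (11 up and 3 down adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.22 with an estimated correlation). Called members include Myog (2.78 ± 0.20) and Msc (2.34 ± 0.32). The myogenic regulator call was lost with the values as deposited, the 5 high-ratio arrays left out and only the compared groups in the fit (adjusted p = 0.055 to 0.069).

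Of the 35 mitosis genes measured, 33 rose, 0 fell and 2 did not pass (35 adjusted over the list alone, camera adjusted p = 6.9e-18). These include Cks2 (2.79 ± 0.18) and Cenpa (2.71 ± 0.20). Of the 33 DNA replication genes measured, 23 rose, 0 fell and 10 did not pass (25 adjusted over the list alone, camera adjusted p = 3.5e-09). Examples are Rrm2 (2.91 ± 0.18) and Mcm6 (2.90 ± 0.51). Of the 31 macrophage genes measured, 29 rose, 0 fell and 2 did not pass (30 adjusted over the list alone, camera adjusted p = 3.1e-22). Called members include Lgals3 (4.57 ± 0.26) and Gpnmb (4.84 ± 0.34). Of the 13 neutrophil genes measured, 7 rose, 0 fell and 6 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0070, adjusted p = 0.095 with an estimated correlation). These include Chil3 (3.32 ± 0.38) and S100a9 (2.86 ± 0.55). Of the 30 chemokine and cytokine genes measured, 13 rose, 0 fell and 17 did not pass (13 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.082 with an estimated correlation). Examples are Ccl2 (3.41 ± 0.45) and Tgfb1 (2.60 ± 0.25). Of the 41 extracellular matrix and fibroblast genes measured, 24 rose, 3 fell and 14 did not pass (25 up and 3 down adjusted over the list alone, camera adjusted p = 3.1e-05, adjusted p = 0.14 with an estimated correlation). Called members include Timp1 (2.91 ± 0.24) and Tnc (2.61 ± 0.25). Of the 21 TGF-beta and Wnt targets measured, 10 rose, 1 fell and 10 did not pass (11 up and 1 down adjusted over the list alone, camera adjusted p = 0.0055). These include Ltbp2 (3.32 ± 0.18) and Sfrp2 (3.03 ± 0.24). Of the 25 amino acid and ER stress genes measured, 14 rose, 2 fell and 9 did not pass (14 up and 2 down adjusted over the list alone, camera adjusted p = 0.0055). Examples are Psat1 (2.18 ± 0.22) and Pdia6 (1.73 ± 0.16). Of the 29 cytosolic ribosome genes measured, 14 rose, 0 fell and 15 did not pass (14 adjusted over the list alone, camera adjusted p = 0.0042, adjusted p = 0.21 with an estimated correlation). An example is Rps9 (1.07 ± 0.19).

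Of the 12 adipocyte genes measured, 0 rose, 6 fell and 6 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.11 with an estimated correlation). An example is Car3 (-2.10 ± 0.22). Of the 16 circadian clock genes measured, 0 rose, 5 fell and 11 did not pass (5 adjusted over the list alone, camera adjusted p = 0.0070, adjusted p = 0.088 with an estimated correlation). Examples are Dbp (-2.52 ± 0.25) and Nr1d1 (-2.04 ± 0.34). Of the 11 Schwann cell and nerve genes measured, 0 rose, 3 fell and 8 did not pass (5 adjusted over the list alone, camera adjusted p = 0.040, adjusted p = 0.17 with an estimated correlation). An example is Pmp22 (-1.23 ± 0.28). The Schwann cell and nerve call was lost with the values as deposited and the mean of all probe sets and without control day 0 replicate 2 and control day 3 replicate 2 (adjusted p = 0.056 to 0.12). Of the 28 Rb/E2F pathway genes, which control entry into the cell cycle measured, 11 rose, 2 fell and 15 did not pass (11 up and 3 down adjusted over the list alone, camera adjusted p = 0.044, adjusted p = 0.084 with an estimated correlation). These include Cdk4 (1.67 ± 0.16) and E2f6 (-2.59 ± 0.23). The Rb/E2F call was lost with median scaling, the values as deposited and the mean of all probe sets and without control day 0 replicate 2 and control day 3 replicate 2 (adjusted p = 0.058 to 0.11). Of the 20 nuclear envelope and lamina genes measured, 6 rose, 2 fell and 12 did not pass (6 up and 2 down adjusted over the list alone, camera adjusted p = 0.19). Examples are Lmna (2.13 ± 0.22) and Lmnb2 (2.04 ± 0.27). Of the 27 interferon response genes measured, 5 rose, 1 fell and 21 did not pass (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.20). An example is Iigp1 (-1.70 ± 0.39).

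Of the 20 p53 targets measured, 4 rose, 3 fell and 13 did not pass (4 up and 3 down adjusted over the list alone, camera adjusted p = 0.75). An example is Pmaip1 (3.65 ± 0.27). Of the 26 immediate early and MAPK genes measured, 8 rose, 3 fell and 15 did not pass (8 up and 3 down adjusted over the list alone, camera adjusted p = 0.19). An example is Nr4a1 (-2.33 ± 0.31). Of the 16 endothelial genes measured, 1 rose, 3 fell and 12 did not pass (1 up and 3 down adjusted over the list alone, camera adjusted p = 0.055). An example is Aqp1 (-1.46 ± 0.16). Of the 17 lymphocyte genes measured, 1 rose, 0 fell and 16 did not pass (1 adjusted over the list alone, camera adjusted p = 0.67). Of the 5 erythroid genes measured, 0 rose, 0 fell and 5 did not pass (0 adjusted over the list alone, camera adjusted p = 0.39). The sex-linked list had fewer than 5 measured genes and was not tested, and its members Eif2s3y (-0.44 ± 0.27, adjusted p = 0.23) and Kdm5d (-0.12 ± 0.25, adjusted p = 0.77) did not pass.

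On day 4 control muscle stood close to day 3: 2178 genes were higher and 1592 lower than on day 0, of which 1910 and 1331 had also passed on day 3, where 438 and 225 are the numbers for independent lists and the day 0 arrays are shared. The largest rises were in Gpnmb, Tnnt2, Lgals3, Myh3, Mpeg1, Myh8, Myl4, Fcer1g, Chrng and P2ry6 (4.97 ± 0.34 in Gpnmb to 4.07 ± 0.46 in P2ry6). The largest falls were in Myl3, Phkg1, Tuba8, Myl2, Mlf1, Rpl3l, Ppp1r1a, Chad and Cox7a1 (-4.78 ± 0.31 in Myl3 to -3.48 ± 0.27 in Cox7a1) and 1 unnamed cDNA. All 19 genes named with a call here kept it with any array left out.

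From day 3 to day 4 in control, 5 genes rose and 0 fell by limma, with 531 genes at an unadjusted p under 0.05. These 5 were Atp1b4 (3.10 ± 0.35, adjusted p = 1.5e-04), a muscle protein related to the sodium pump, Myh7 (1.57 ± 0.27, adjusted p = 0.032), the slow myosin, Myh8 (1.32 ± 0.22, adjusted p = 0.031), Islr (0.96 ± 0.17, adjusted p = 0.032) and Rflnb (0.90 ± 0.16, adjusted p = 0.035). Among mature fast contractile genes, 0 of 27 rose, 0 fell and 27 did not pass (6 adjusted over the list alone, camera adjusted p = 2.8e-14). Actn2 (1.07 ± 0.21, adjusted p = 0.098) came nearest. Among slow fiber genes, 1 of 13 rose, 0 fell and 12 did not pass (6 adjusted over the list alone, camera adjusted p = 3.7e-11). Among mitosis genes, 0 of 35 rose, 0 fell and 35 did not pass (0 adjusted over the list alone, camera adjusted p = 4.1e-09). The list's median log2 was -0.34. The count of 5 genes was 1 without control day 3 replicate 1, 10 without control day 3 replicate 2, 2 without control day 4 replicate 1 and 2 without control day 4 replicate 2. The number was 1 with median scaling, 1 with no intensity trend, 14 with the Gapdh ratio as a covariate and 1 with only the compared groups in the fit. Of the 5 genes named with a call here, 1 kept it with any array left out, and 4 lost it without control day 3 replicate 1.

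The same change within emerin KO muscle was large: 2663 genes rose and 2481 fell from day 0 to day 3. The largest rises were in Chrng, Arg1, Hmox1, Lgals3, Tubb6, Myog, Cotl1, Runx1, Cyba and Fermt3 (5.54 ± 0.30 in Chrng to 4.87 ± 0.35 in Fermt3). Of 2 other probe sets of Chrng, 1 went the other way (-0.28). The largest falls were in Myl3, Rpl3l, Mlf1, Myl2, Cox8b, Tmem38a, Kcna7, Apobec2, Phkg1 and Mpc1 (-5.95 ± 0.29 in Myl3 to -4.46 ± 0.34 in Mpc1). Mitosis genes counted 35, of which 29 rose, 0 fell and 6 did not pass (31 adjusted over the list alone, camera adjusted p = 1.9e-16). Called members include Top2a (3.63 ± 0.15) and Cdk1 (4.13 ± 0.36). Among interferon response genes, 17 of 27 rose, 0 fell and 10 did not pass (19 adjusted over the list alone, camera adjusted p = 5.0e-05, adjusted p = 0.16 with an estimated correlation). These include Oas1a (3.52 ± 0.36) and Bst2 (2.17 ± 0.29). Of the control response, 1813 rises and 1374 falls also passed here, where 535 and 351 are the numbers for independent lists, and the correlation over all genes was 0.845, genes not being independent replicates. Eif2s3y (-0.86 ± 0.24) and Kdm5d (-0.70 ± 0.23; 1 of 2 other probe sets 0.37), of the sex-linked list, fell as well. The day 3 arrays of this change are those of the high Gapdh 3'/5' ratio (mean 4.83 against 1.13 on day 0), and 2809 genes passed with the Gapdh ratio as a covariate. Of the 26 genes named with a call here, 25 kept it with any array left out, and 1 lost it without emerin KO day 0 replicate 1.

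Within lamin A/C KO muscle 2613 genes rose and 2189 fell from day 0 to day 3. The largest rises were in Arg1, Gpnmb, Chil3, Chrng, Fads3, Kcnn4, Lst1, Mpeg1, Fcer1g and Slc15a3 (6.12 ± 0.35 in Arg1 to 3.96 ± 0.34 in Slc15a3). Of 2 other probe sets of Chrng, 1 went the other way (-0.66). The largest falls were in Myl3, Rpl3l, Myl2, Ckmt2, Mlf1, Phkg1, Prkcq, Acacb and Myh7 (-5.80 ± 0.26 in Myl3 to -4.23 ± 0.22 in Myh7) and 1 unnamed cDNA. Among regenerating myofiber genes, 12 of 23 rose, 4 fell and 7 did not pass (12 up and 4 down adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.089 with an estimated correlation). An example is Mymk (3.59 ± 0.20). Among macrophage genes, 30 of 31 rose, 0 fell and 1 did not pass (30 adjusted over the list alone, camera adjusted p = 1.7e-21). An example is Cd68 (3.72 ± 0.16). With the control response this list shared 1919 rises and 1380 falls, where 525 and 310 are the numbers for independent lists, and the correlation over all genes was 0.886. All 21 genes named with a call here kept it with any array left out.

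The comparison of emerin KO with control before injury asks what the lack of emerin does to resting muscle. Matrix and connective tissue genes were lower in emerin KO on day 0. Among extracellular matrix and fibroblast genes, 0 of 41 were higher, 24 were lower and 17 did not pass (31 adjusted over the list alone, camera adjusted p = 2.3e-37). These include Postn (-1.92 ± 0.25), Col12a1 (-2.96 ± 0.40), Bgn (-1.92 ± 0.22) and Timp1 (-1.56 ± 0.24). Regenerating myofiber genes counted 23, of which 0 were higher, 7 were lower and 16 did not pass (13 adjusted over the list alone, camera adjusted p = 7.5e-14). Examples are Igf2 (-1.80 ± 0.21), Mybph (-1.74 ± 0.22), Mest (-1.46 ± 0.25) and Myh3 (-1.2 ± 0.32). For mitosis genes, 1 of 35 was higher, 7 were lower and 27 did not pass (1 up and 9 down adjusted over the list alone, camera adjusted p = 1.4e-05). Called members include Cdk1 (-1.76 ± 0.40) and Mad2l1 (-1.67 ± 0.19). Across all genes, 137 were higher and 227 lower in emerin KO. Rises were largest in Chac1 (3.08 ± 0.38), Ercc6l (2.58 ± 0.65), Kiss1r (2.24 ± 0.34), Opn1mw (2.24 ± 0.36), Rasd2 (2.23 ± 0.56), Fbxo32 (2.01 ± 0.45), H2-Aa (2.0 ± 0.32), Fam83g (1.96 ± 0.50) and Usp38 (1.90 ± 0.36) and 1 unnamed clone. Falls were largest in Gdpd3 (-4.00 ± 0.23), Mfap4 (-3.98 ± 0.52), Col12a1 (-2.96 ± 0.40), Rbp7 (-2.61 ± 0.32), Tnfrsf12a (-2.35 ± 0.30), Gga1 (-2.24 ± 0.32), Kcne1l (-2.21 ± 0.55) and Blvrb (-2.15 ± 0.36) and 2 unnamed cDNAs. Gapdh 3'/5' ratios were 0.914 and 1.34 in emerin KO and 0.829 and 0.949 in control. With them as a covariate 364 genes passed, 324 the same. The count of 364 was 159 without control day 0 replicate 1, 199 without control day 0 replicate 2, 563 without emerin KO day 0 replicate 1 and 167 without emerin KO day 0 replicate 2. It was 6 with only the compared groups in the fit. The share of higher genes was 37.6%, against 23.8% of 298 with median scaling. Of the 26 genes named with a call here, 18 kept it with any array left out, and 8 lost it without control day 0 replicate 1.

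On day 3 after injury 824 genes were higher and 996 lower in emerin KO than in control, in the arrays whose mean Gapdh 3'/5' ratio was 4.83 in emerin KO and 0.966 in control. Interferon-induced genes were higher, and matrix, regenerating myofiber and contractile genes lower. Interferon response genes counted 27, of which 13 were higher, 0 were lower and 14 did not pass (18 adjusted over the list alone, camera adjusted p = 6.1e-09, adjusted p = 0.15 with an estimated correlation). These include Rsad2 (2.33 ± 0.37), Rtp4 (2.33 ± 0.48), Oasl2 (2.17 ± 0.33) and Bst2 (1.69 ± 0.29). Extracellular matrix and fibroblast genes counted 41, of which 0 were higher, 20 were lower and 21 did not pass (23 adjusted over the list alone, camera adjusted p = 4.1e-11, adjusted p = 0.11 with an estimated correlation). Examples are Postn (-2.87 ± 0.23), Thbs1 (-2.54 ± 0.40) and Tnc (-2.44 ± 0.23). For regenerating myofiber genes, 2 of 23 were higher, 10 were lower and 11 did not pass (2 up and 11 down adjusted over the list alone, camera adjusted p = 7.2e-04, adjusted p = 0.15 with an estimated correlation). Called members include Sln (-3.58 ± 0.22), Igf2 (-2.13 ± 0.19), Myh8 (-1.81 ± 0.20) and Myl4 (-1.30 ± 0.21). Mature fast contractile genes counted 27, of which 1 was higher, 11 were lower and 15 did not pass (1 up and 15 down adjusted over the list alone, camera adjusted p = 2.4e-06, adjusted p = 0.24 with an estimated correlation). These include Myl1 (-2.54 ± 0.26) and Myot (-1.37 ± 0.28). The list's median of -0.55 was -0.84 without control day 3 replicate 1 and -0.30 without replicate 2. Among DNA replication genes, 9 of 33 were higher, 0 were lower and 24 did not pass (10 adjusted over the list alone, camera adjusted p = 5.5e-04, adjusted p = 0.090 with an estimated correlation). Examples are Mcm2 (1.5 ± 0.51) and Mcm7 (1.04 ± 0.22). Among myogenic regulators, 5 of 28 were higher, 6 were lower and 17 did not pass (5 up and 6 down adjusted over the list alone, camera adjusted p = 0.97). Called members include Myf6 (-1.67 ± 0.23), Cdh15 (1.13 ± 0.16) and Myog (1.13 ± 0.18). Macrophage genes counted 31, of which 8 were higher, 3 were lower and 20 did not pass (9 up and 4 down adjusted over the list alone, camera adjusted p = 0.070). These include Cd163 (1.97 ± 0.27), Laptm5 (1.83 ± 0.24) and Cd53 (-1.54 ± 0.29). With the Gapdh ratio as a covariate camera gave an adjusted p of 7.3e-04 for the macrophage list. Highest against control stood Trim34a (3.04 ± 0.37), Slfn8 (2.66 ± 0.37), Rpgrip1 (2.63 ± 0.88), Ptpn23 (2.56 ± 0.44), Exosc9 (2.43 ± 0.22), Rsad2 (2.33 ± 0.37), Rtp4 (2.33 ± 0.48), Cbr2 (2.31 ± 0.30) and Slfn1 (2.22 ± 0.38) and 1 gene model. Lowest stood Mfap4 (-3.83 ± 0.48), Sln (-3.58 ± 0.22), Il13ra1 (-3.15 ± 0.53), Itm2a (-3.05 ± 0.30), Tmem38a (-2.90 ± 0.59), Postn (-2.87 ± 0.23), Cdh11 (-2.62 ± 0.29), Thbs1 (-2.54 ± 0.40), C1qtnf3 (-2.54 ± 0.35) and Myl1 (-2.54 ± 0.26). With the ratio as a covariate 9 genes passed, against 364 on day 0 and 20 on day 4, the slope of the effects on those without it was 0.534, and Tmem38a turned to 0.79. The count of 1820 was 1007 without control day 3 replicate 1 and 781 without control day 3 replicate 2, and 1197 with only the compared groups in the fit. Of the 35 genes named with a call here, 31 kept it with any array left out and 4 with the covariate.

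On day 4, 288 genes were higher and 367 lower in emerin KO, with a Gapdh 3'/5' ratio of 1.40 to 5.30 in emerin KO and 0.932 to 1.23 in control. For interferon response genes, 8 of 27 were higher, 0 were lower and 19 did not pass (14 adjusted over the list alone, camera adjusted p = 1.5e-08, adjusted p = 0.20 with an estimated correlation). Examples are Rsad2 (1.66 ± 0.37) and Bst2 (1.45 ± 0.29). For macrophage genes, 5 of 31 were higher, 0 were lower and 26 did not pass (6 adjusted over the list alone, camera adjusted p = 0.024, adjusted p = 0.51 with an estimated correlation). The macrophage call was lost with quantile normalization and without control day 4 replicate 2 and emerin KO day 4 replicate 2 (adjusted p = 0.056 to 0.36). Among chemokine and cytokine genes, 5 of 30 were higher, 0 were lower and 25 did not pass (12 adjusted over the list alone, camera adjusted p = 8.9e-05, adjusted p = 0.15 with an estimated correlation). These include Ccl6 (1.70 ± 0.30) and Cxcl10 (1.59 ± 0.38). For extracellular matrix and fibroblast genes, 0 of 41 were higher, 11 were lower and 30 did not pass (16 adjusted over the list alone, camera adjusted p = 1.6e-09, adjusted p = 0.16 with an estimated correlation). Examples are Col12a1 (-1.62 ± 0.37) and Postn (-1.43 ± 0.23). For mature fast contractile genes, 0 of 27 were higher, 3 were lower and 24 did not pass (8 adjusted over the list alone, camera adjusted p = 6.0e-05, adjusted p = 0.38 with an estimated correlation). Called members include Pvalb (-1.71 ± 0.48), Myot (-1.59 ± 0.28) and Ldb3 (-1.29 ± 0.26). Subunits of the fetal acetylcholine receptor, Chrng (1.65 ± 0.30) and Chrnd (1.63 ± 0.37), were higher (1 of 2 other Chrng probe sets was lower, -0.31), and the slow fiber genes Myh7 (-1.70 ± 0.25), Myl3 (-1.64 ± 0.29) and Myl2 (-1.52 ± 0.39) were lower. Most raised were Cyp4f18, Saa3, Aoah, Ifi27l2a, Cbr2, Slfn4, Slfn8, Ncapg2, Ccl6 and Ly86 (2.25 ± 0.48 in Cyp4f18 to 1.70 ± 0.26 in Ly86). Falls were largest in Hal, Gdpd3, Cap1, Tmem38a, Moxd1, Nfia, Aspn, Itm2a, Sln and Atp1b4 (-3.0 ± 0.57 in Hal to -2.15 ± 0.32 in Atp1b4). The count of 655 was 76 without control day 4 replicate 1, 292 without control day 4 replicate 2, 241 without emerin KO day 4 replicate 1, 1225 without emerin KO day 4 replicate 2 and 200 without emerin KO day 4 replicate 3. The number was 377 with median scaling, 20 with the Gapdh ratio as a covariate and 182 with only the compared groups in the fit. Of the 34 genes named with a call here, 14 kept it with any array left out and 5 with the covariate.

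Averaged over the 3 days, 1249 genes were higher and 1288 lower in emerin KO than in control, over arrays of which those of day 3 and day 4 carry the high Gapdh 3'/5' ratios. Of the 41 extracellular matrix and fibroblast genes measured, 0 were higher, 31 were lower and 10 did not pass (33 adjusted over the list alone, camera adjusted p = 1.2e-24). These include Col12a1 (-2.27 ± 0.22) and Postn (-2.07 ± 0.13). Of the 27 interferon response genes measured, 15 were higher, 0 were lower and 12 did not pass (17 adjusted over the list alone, camera adjusted p = 3.8e-07, adjusted p = 0.24 with an estimated correlation). Examples are Rsad2 (1.37 ± 0.22) and Oasl2 (1.32 ± 0.19). Of the 23 regenerating myofiber genes measured, 3 were higher, 12 were lower and 8 did not pass (3 up and 13 down adjusted over the list alone, camera adjusted p = 2.4e-05, adjusted p = 0.12 with an estimated correlation). Called members include Igf2 (-1.45 ± 0.11) and Mest (-1.29 ± 0.13). The list differed by -0.70, -0.56 and -0.01 on days 0, 3 and 4. Raised most were Trim34a, Slfn8, Cbr2, Cyp4f18, Slfn1, Kiss1r, Exosc9, Oas3, Rpgrip1 and Trmt1 (2.03 ± 0.22 in Trim34a to 1.47 ± 0.16 in Trmt1). Lowered most were Mfap4, Gdpd3, Col12a1, Itm2a, Sln, Postn, Cap1, Tmem38a, Aspn and C1qtnf3 (-3.31 ± 0.28 in Mfap4 to -1.94 ± 0.21 in C1qtnf3). Emd itself differed by -1.28 ± 0.16 (adjusted p = 1.0e-05) and Lmna by -0.02 ± 0.12 (adjusted p = 0.93). With the Gapdh ratio as a covariate 108 genes passed, and Tmem38a turned to 0.16. Of the 25 genes named with a call here, 24 kept it with any array left out and 15 with the covariate.

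**Figure D3:**
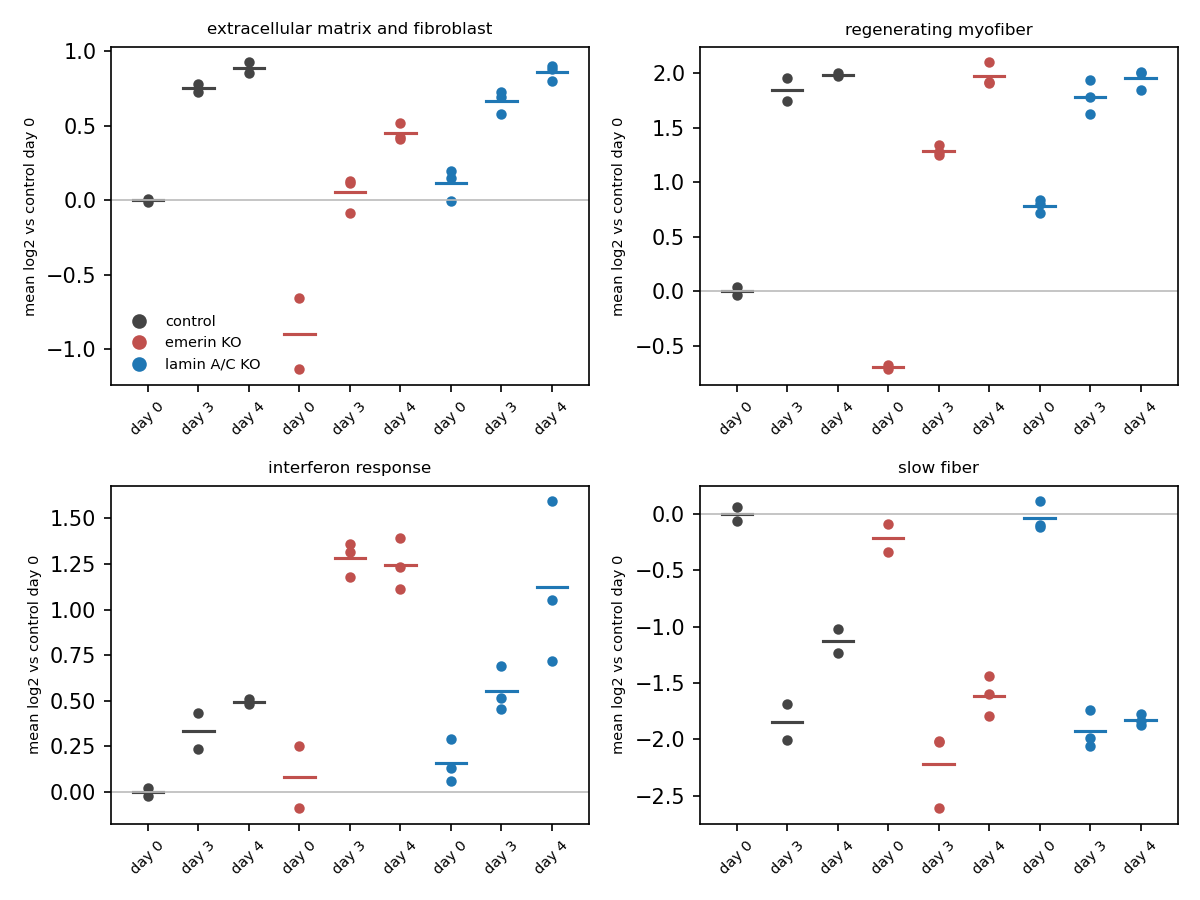
Mean log2 level of 4 gene lists on each array relative to the control day 0 mean, by genotype and day, with a bar at each group mean (n = 2 or 3). The emerin KO day 0 arrays lie under the control day 0 arrays for the extracellular matrix and fibroblast list, and the lamin A/C KO day 0 arrays lie above them for the regenerating myofiber list.

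On day 0, lamin A/C KO muscle (described as 0 days after injection) held more transcript of genes of regenerating and denervated muscle than control (described as not injected). Among regenerating myofiber genes, 7 of 23 were higher, 0 were lower and 16 did not pass (14 adjusted over the list alone, camera adjusted p = 1.1e-16). These include Sln (3.16 ± 0.22), Ankrd1 (2.33 ± 0.26), Myl4 (1.80 ± 0.21) and Myh8 (1.52 ± 0.20). Among denervation and atrophy genes, 4 of 20 were higher, 0 were lower and 16 did not pass (9 adjusted over the list alone, camera adjusted p = 1.6e-09). The higher ones are Sln (in both lists), Mt2 (1.56 ± 0.23), Cdkn1a (1.52 ± 0.25) and Chrna1 (0.64 ± 0.15). Among p53 targets, 2 of 20 were higher, 0 were lower and 18 did not pass (5 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.24 with an estimated correlation). They are Cdkn1a again and Sesn1 (0.73 ± 0.17). Of the 31 macrophage genes measured, 3 were higher, 0 were lower and 28 did not pass (6 adjusted over the list alone, camera adjusted p = 4.1e-06, adjusted p = 0.27 with an estimated correlation). These include Lgals3 (1.55 ± 0.23), C1qa (0.80 ± 0.14) and Lyz2 (0.79 ± 0.17). The macrophage call was lost without control day 0 replicate 1 (adjusted p = 0.21). Among all genes, 84 were higher and 16 lower. Rises were largest in Sln (3.16 ± 0.22), Serpinb1a (2.72 ± 0.26), Cpne2 (2.46 ± 0.34), Ankrd1 (2.33 ± 0.26), S100a4 (2.20 ± 0.23), Pim1 (1.95 ± 0.40), Hspa1b (1.91 ± 0.23), Uchl1 (1.90 ± 0.27) and Rrad (1.86 ± 0.39) and 1 gene model. Apart from Lmna, falls were largest in Arhgap27 (-1.54 ± 0.27), Slc5a11 (-1.47 ± 0.35), Traf5 (-1.44 ± 0.28), Sugp2 (-1.21 ± 0.26), Hvcn1 (-1.15 ± 0.24), Acvr1b (-1.09 ± 0.16), Itgb6 (-0.94 ± 0.23), Mmd (-0.88 ± 0.18) and Snhg6 (-0.84 ± 0.20). The other probe sets of Acvr1b (0.26) and Myl4 (-0.56) went the other way. The count of 100 was 54 without control day 0 replicate 1, 48 without control day 0 replicate 2 and 62 without lamin A/C KO day 0 replicate 2. The number was 50 with median scaling and 36 with only the compared groups in the fit. Of the 28 genes named with a call here, 11 kept it with any array left out, and 14 lost it without control day 0 replicate 2.

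After injury few single genes differed between lamin A/C KO and control by limma. On day 3 the 3 genes past the threshold were all lower in lamin A/C KO: Lmna, Aspn (-1.34 ± 0.23, adjusted p = 0.026) and Cpe (-1.08 ± 0.18, adjusted p = 0.023), a peptide-processing enzyme, with 809 genes at an unadjusted p under 0.05. Among macrophage genes, 0 of 31 were higher, 0 were lower and 31 did not pass (4 adjusted over the list alone, camera adjusted p = 3.1e-05, adjusted p = 0.43 with an estimated correlation). Cd163 (1.43 ± 0.27, adjusted p = 0.060) came nearest. The day 3 count was 7 without control day 3 replicate 1 and 1 without lamin A/C KO day 3 replicate 3. It was 10 with the values as deposited, 1 with the mean of all probe sets, 1 with no intensity trend, 1 with a replicate block and 1 with only the compared groups in the fit. Aspn lost its call with median scaling, no intensity trend, a replicate block, the Gapdh ratio as a covariate, the 5 high-ratio arrays left out and only the compared groups in the fit and without control day 3 replicate 1, control day 3 replicate 2, lamin A/C KO day 3 replicate 2 and lamin A/C KO day 3 replicate 3 (adjusted p = 0.061 to 0.34). Cpe lost it with median scaling, the mean of all probe sets, no intensity trend, a replicate block and only the compared groups in the fit and without control day 3 replicate 2, lamin A/C KO day 3 replicate 1 and lamin A/C KO day 3 replicate 3 (adjusted p = 0.056 to 0.58).

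On day 4 the 5 genes past the threshold between lamin A/C KO and control, all lower in lamin A/C KO, were Lmna, the slow fiber chains Myh7 (-2.50 ± 0.25, adjusted p = 8.2e-06), Myl3 (-2.56 ± 0.29, adjusted p = 4.4e-05) and Myl2 (-2.24 ± 0.39, adjusted p = 0.023), and Cd5l (-1.48 ± 0.24, adjusted p = 0.012), a secreted macrophage protein, with 540 genes at an unadjusted p under 0.05. Slow fiber genes counted 13, of which 0 were higher, 3 were lower and 10 did not pass (3 adjusted over the list alone, camera adjusted p = 7.7e-07, adjusted p = 0.11 with an estimated correlation). Among interferon response genes, 0 of 27 were higher, 0 were lower and 27 did not pass (10 adjusted over the list alone, camera adjusted p = 7.6e-18, adjusted p = 0.050 with an estimated correlation). The list's median was 0.53, and 0.37 without lamin A/C KO day 4 replicate 2, whose list mean of 1.59 stood above the 0.72 and 1.05 of the other 2 arrays, with Ifit2 at 1.62 ± 0.42 (adjusted p = 0.48). The call of Cd5l was lost with the 5 high-ratio arrays left out and only the compared groups in the fit and without control day 4 replicate 1 and lamin A/C KO day 4 replicate 1 (adjusted p = 0.057 to 0.26). That of Myl2 was lost with median scaling and no intensity trend and without control day 4 replicate 1, control day 4 replicate 2, lamin A/C KO day 4 replicate 1 and lamin A/C KO day 4 replicate 2 (adjusted p = 0.069 to 0.32).

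Averaged over the days, 45 genes were higher and 26 lower in lamin A/C KO than in control. Macrophage genes counted 31, of which 3 were higher, 0 were lower and 28 did not pass (11 adjusted over the list alone, camera adjusted p = 8.1e-14). Examples are Cd163 (0.79 ± 0.16), Lgals3 (0.60 ± 0.13) and C1qa (0.45 ± 0.08). Chemokine and cytokine genes counted 30, of which 3 were higher, 0 were lower and 27 did not pass (6 adjusted over the list alone, camera adjusted p = 2.5e-07). An example is Ccl6 (0.85 ± 0.17). Regenerating myofiber genes counted 23, of which 3 were higher, 0 were lower and 20 did not pass (8 adjusted over the list alone, camera adjusted p = 5.7e-09). This mean rests on day 0, where the list lay at 0.78 in lamin A/C KO above the control day 0 mean, while it lay at 1.79 against 1.85 in control on day 3 and 1.95 against 1.99 on day 4. Interferon response genes counted 27, of which 1 was higher, 0 were lower and 26 did not pass (10 adjusted over the list alone, camera adjusted p = 6.9e-11, adjusted p = 0.085 with an estimated correlation). An example is Ifit1 (0.75 ± 0.17). Rises were largest in Cpne2, Kiss1r, S100a4, Slfn1, Rps25, Ccl6, Mt2, Ms4a4c and Cd163 (1.33 ± 0.20 in Cpne2 to 0.79 ± 0.16 in Cd163) and 1 unnamed cDNA. Besides Lmna (adjusted p = 2.3e-17), falls were largest in Myl3, Myh7, Rpl3l, Cd5l, Ccn3, Dbp, Capn3, Itgbl1 and Zfp131 (-1.19 ± 0.17 in Myl3 to -0.60 ± 0.12 in Zfp131). Emd differed by 0.09 ± 0.16 (adjusted p = 0.94). The count of 71 was 34 without control day 0 replicate 2, 39 without control day 3 replicate 2, 21 without control day 4 replicate 1, 21 without control day 4 replicate 2 and 47 without lamin A/C KO day 0 replicate 2. It was 20 with median scaling, 42 with no intensity trend and 110 with only the compared groups in the fit. The share of higher genes was 63.4%, against 75% of 20 with median scaling. Of the 22 genes named with a call here, 9 kept it with any array left out, and 12 lost it without control day 4 replicate 1.

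Set directly against each other over the 3 days, the knockouts differed in 1344 genes that were higher and 1339 that were lower in emerin KO. Among extracellular matrix and fibroblast genes, 0 of 41 were higher, 33 were lower and 8 did not pass (34 adjusted over the list alone, camera adjusted p = 1.1e-26). Called members include Postn (-2.05 ± 0.12), Thbs1 (-1.72 ± 0.22), Col12a1 (-1.73 ± 0.20) and Tnc (-1.64 ± 0.12). For regenerating myofiber genes, 2 of 23 were higher, 17 were lower and 4 did not pass (2 up and 18 down adjusted over the list alone, camera adjusted p = 1.2e-12). These include Sln (-2.82 ± 0.12), Igf2 (-1.61 ± 0.10) and Mest (-1.21 ± 0.12). This list lay at -0.70 in emerin KO against 0.78 in lamin A/C KO on day 0, 1.29 against 1.79 on day 3 and 1.98 against 1.95 on day 4. Besides Lmna (adjusted p = 5.6e-18), rises were largest in Rpgrip1, Trim34a, Slfn8, Rasd2, Chad, Snhg6, Exosc9, Alpk3 and Rab6b (2.11 ± 0.47 in Rpgrip1 to 1.36 ± 0.24 in Rab6b). Lowest against lamin A/C KO stood Gdpd3, Sln, Mfap4, Hal, Serpina3n, Cap1, Itm2a, Postn, Aspn and Col12a1 (-3.0 ± 0.11 in Gdpd3 to -1.73 ± 0.20 in Col12a1). Emd differed by -1.37 ± 0.14 (adjusted p = 9.7e-07). The Gapdh 3'/5' ratio was 3.62 to 6.09 in emerin KO and 1.21 to 1.64 in lamin A/C KO on day 3, and with the ratio as a covariate 153 genes passed. The share of higher genes was 50.1%, against 39.8% of 2254 with median scaling. All 25 genes named with a call here kept it with any array left out and 17 with the covariate.

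The knockouts were each compared with the same 6 control arrays, so their differences from control are correlated by construction. Over the 3-day means, 25 genes were higher in both knockouts (5.03 for independent lists) and 14 were lower in both (3.00), while Cd5l, Hspa1b, Myl4, Rprd1a and Sln passed in opposite directions. On day 0, 11 genes were higher in both (1.03) and 2, Scd2 and Slc5a11, were lower in both (0.325), while Chrna1, Igf2, Psat1, Snhg6 and Tnfrsf12a went in opposite directions. Aspn and Cpe were lower in both on day 3, and Myh7, Myl2 and Myl3 on day 4. The covariance of the effects over all genes was 0.0282, against a mean of 0.0197 in 100 simulations with no shared effect and the same shared controls (0.000132 to 0.0813), so it lay within that range. With the controls split so that each knockout had its own, the covariance over 8 splits averaged 0.0118 (-0.00191 to 0.0217).

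Interactions tested if responses to injury differed from control, which a day 0 difference alone can give. In emerin KO the change from day 0 to day 3 differed from that in control in 295 genes, 159 upward and 136 downward, with day 3 arrays of the high Gapdh 3'/5' ratio. DNA replication genes counted 33, of which 5 changed more upward, 0 changed more downward and 28 did not pass (5 adjusted over the list alone, camera adjusted p = 3.9e-05). Examples are Mcm7 (1.75 ± 0.33) and Rrm2 (1.57 ± 0.24). Of the 35 mitosis genes measured, 6 changed more upward, 1 changed more downward and 28 did not pass (10 up and 1 down adjusted over the list alone, camera adjusted p = 6.0e-05). Called members include Birc5 (1.95 ± 0.29) and Ccnb2 (1.41 ± 0.34). This list lay at -0.33 on day 0 (control 0) and 1.86 on day 3 (control 1.80), so it differs mostly on day 0, as does Chac1. For interferon response genes, 3 of 27 changed more upward, 0 changed more downward and 24 did not pass (8 adjusted over the list alone, camera adjusted p = 4.6e-07, adjusted p = 0.22 with an estimated correlation). An example is Oas1a (2.03 ± 0.53). The largest upward differences were in Rtp4, Xdh, Gga1, Gdpd3, Incenp, Rsad2, Myog and Cnp (3.08 ± 0.71 in Rtp4 to 2.17 ± 0.35 in Cnp) and 2 gene models. The largest downward differences were in Chac1, Il13ra1, Sln, Cldn2, Pdzrn3, Pla2g7, Opn1mw, Pfkfb3, Mmp13 and Myl1 (-3.07 ± 0.51 in Chac1 to -2.06 ± 0.39 in Myl1). The 2 other probe sets of Incenp went the other way (-0.94 and -0.03). Emd (-0.92 ± 0.40, adjusted p = 0.23) and Lmna (0.51 ± 0.29, adjusted p = 0.39) did not pass. The count of 295 was 110 without control day 0 replicate 1, 128 without control day 0 replicate 2, 143 without control day 3 replicate 1, 57 without control day 3 replicate 2, 455 without emerin KO day 0 replicate 1, 121 without emerin KO day 0 replicate 2, 170 without emerin KO day 3 replicate 1, 149 without emerin KO day 3 replicate 2 and 581 without emerin KO day 3 replicate 3. It was 139 with median scaling, 169 with no intensity trend, 16 with the Gapdh ratio as a covariate and 68 with only the compared groups in the fit. The share of upward differences was 53.9%, against 78.4% of 139 with median scaling. Of the 23 genes named with a call here, 13 kept it with any array left out and 6 with the covariate.

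In lamin A/C KO the change from day 0 to day 3 differed from that in control in 19 genes, 1 upward and 18 downward. Of the 84 genes higher in lamin A/C KO on day 0, 37 rose and 15 fell there from day 0 to day 3. Of the 23 regenerating myofiber genes measured, 0 changed more upward, 6 changed more downward and 17 did not pass (8 adjusted over the list alone, camera adjusted p = 1.6e-12). Examples are Sln, Ankrd1, Myh8 and Myl4, which differ mostly on day 0 (Sln 3.16, -0.67 on day 3). Denervation and atrophy genes counted 20, of which 0 changed more upward, 1 changed more downward (Sln) and 19 did not pass (6 adjusted over the list alone, camera adjusted p = 1.6e-06). Besides Lmna (adjusted p = 1.5e-04), whose mean stays under the minimum signal in lamin A/C KO, the largest downward differences were in Serpinb1a (-3.98 ± 0.37), Sln (-3.82 ± 0.30), Ankrd1 (-2.31 ± 0.36), Myh8 (-2.16 ± 0.28), Uchl1 (-2.14 ± 0.38), Myl4 (-1.98 ± 0.29), Sh3bp4 (-1.89 ± 0.32), Hspa1b (-1.78 ± 0.32) and S100a4 (-1.74 ± 0.32), and the upward one was in Arhgap27 (1.93 ± 0.38). The other probe set of Myl4 went the other way (0.23). Emd differed by -0.13 ± 0.38 (adjusted p = 0.98). The count of 19 was 6 without control day 3 replicate 2, 9 without lamin A/C KO day 0 replicate 1 and 11 without lamin A/C KO day 3 replicate 2. The number was 8 with median scaling and 9 with no intensity trend. Of the 11 genes named with a call here, 5 kept it with any array left out, and 6 lost it without control day 3 replicate 2.

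From day 3 to day 4, emerin KO muscle raised perinatal myosin, sarcolipin, contractile and matrix genes, with 107 genes rising and 24 falling. Among regenerating myofiber genes, 8 of 23 rose, 2 fell and 13 did not pass (14 up and 2 down adjusted over the list alone, camera adjusted p = 8.1e-13). Of the 27 mature fast contractile genes measured, 10 rose, 0 fell and 17 did not pass (18 adjusted over the list alone, camera adjusted p = 4.6e-19). An example is Actn2 (1.55 ± 0.18). Extracellular matrix and fibroblast genes counted 41, of which 3 rose, 0 fell and 38 did not pass (11 adjusted over the list alone, camera adjusted p = 1.1e-12). Called members include Postn (1.46 ± 0.20) and Tnc (1.2 ± 0.21). The largest rises were in Myh8, Mfap4, Sln, Igf2, Myl1, Stbd1, Atp1b4, Casq2, Cldn2 and Itgb1bp2 (2.70 ± 0.18 in Myh8 to 1.64 ± 0.14 in Itgb1bp2). Falls were greatest in Scg3, Cd163, Lmnb2, Myog, Rrm2, Srsf1, Cdh15, Nasp, Clec10a and Fbl (-1.82 ± 0.42 in Scg3 to -0.75 ± 0.15 in Fbl). The other probe sets of Lmnb2 (0.40) and Fbl (0.02) and 1 of 5 of Srsf1 (-0.36 to 0.05) went the other way. Gapdh 3'/5' ratios were 3.62 to 6.09 on day 3 and 1.40 to 5.30 on day 4. The count of 131 was 85 without emerin KO day 3 replicate 2, 74 without emerin KO day 4 replicate 1 and 87 without emerin KO day 4 replicate 2. The number was 79 with median scaling and 42 with only the compared groups in the fit. Of the 23 genes named with a call here, 16 kept it with any array left out, and 7 lost it without emerin KO day 4 replicate 1.

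Lamin A/C KO muscle over the same day raised 144 genes and lowered 84. Among mature fast contractile genes, 7 of 27 rose, 0 fell and 20 did not pass (19 adjusted over the list alone, camera adjusted p = 4.2e-18). These include Myot (1.44 ± 0.25) and Ldb3 (1.22 ± 0.23). Of the 27 interferon response genes measured, 4 rose, 0 fell and 23 did not pass (7 adjusted over the list alone, camera adjusted p = 8.4e-09, adjusted p = 0.11 with an estimated correlation). Examples are Ifit3 (1.25 ± 0.28) and Oasl2 (1.21 ± 0.29). The list's median was 0.60, and 0.39 without lamin A/C KO day 4 replicate 2. For DNA replication genes, 0 of 33 rose, 4 fell and 29 did not pass (10 adjusted over the list alone, camera adjusted p = 7.8e-08). Called members include Mcm5 (-0.84 ± 0.20) and Mcm7 (-0.78 ± 0.20). The largest rises were in Atp1b4, Atp1b2, Aspn, Mfap4, Tmod4, Ifit2, Apobec2, Fabp3, Shisa2 and Myoz1 (2.95 ± 0.28 in Atp1b4 to 1.58 ± 0.20 in Myoz1). Falling most were Cort, Arg1, Itgb7, Chil3, Idi1, Ifitm1, F10, Dok2, Cyp51 and Ccl24 (-1.84 ± 0.45 in Cort to -1.14 ± 0.30 in Ccl24). The Gapdh 3'/5' ratio was 1.21 to 1.64 on day 3, highest on replicate 3, and 0.822 to 0.888 on day 4. With emerin KO, 38 rises (1.38 for independent lists) and 7 falls (0.181) were shared. The count of 228 was 139 without lamin A/C KO day 3 replicate 2, 56 without lamin A/C KO day 3 replicate 3, 136 without lamin A/C KO day 4 replicate 1, 69 without lamin A/C KO day 4 replicate 2 and 130 without lamin A/C KO day 4 replicate 3. The number was 134 with median scaling, 356 with the values as deposited, 137 with no intensity trend, 53 with the Gapdh ratio as a covariate and 380 with only the compared groups in the fit. Of the 26 genes named with a call here, 9 kept it with any array left out and 11 with the covariate. Without lamin A/C KO day 4 replicate 2, 17 lost it.

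Tested as an interaction, the step from day 3 to day 4 differed from control in 5 genes in emerin KO. Igf2 (1.71 ± 0.27, adjusted p = 0.011), Itgb1bp2 (1.47 ± 0.23, adjusted p = 0.011), Stbd1 (1.51 ± 0.26, adjusted p = 0.024) and Apip (1.28 ± 0.23, adjusted p = 0.044) changed more upward, and Myh7 (-2.04 ± 0.35, adjusted p = 0.024) more downward, with 787 genes at an unadjusted p under 0.05. Regenerating myofiber genes counted 23, of which 1 changed more upward, 0 changed more downward and 22 did not pass (9 up and 1 down adjusted over the list alone, camera adjusted p = 4.4e-07, adjusted p = 0.066 with an estimated correlation). That count of 5 was 0 without control day 3 replicate 1, 2 without control day 3 replicate 2, 1 without control day 4 replicate 2, 2 without emerin KO day 3 replicate 1, 3 without emerin KO day 4 replicate 2 and 9 without emerin KO day 4 replicate 3. The number was 8 with quantile normalization, 0 with median scaling, 8 with the values as deposited, 0 with no intensity trend, 9 with a replicate block, 9 with the Gapdh ratio as a covariate and 1 with only the compared groups in the fit. In lamin A/C KO only Myh7 (-2.36 ± 0.35, adjusted p = 0.013) differed, more downward than in control, with 651 genes at an unadjusted p under 0.05. Its call was lost with no intensity trend and only the compared groups in the fit and without control day 3 replicate 1, control day 3 replicate 2, control day 4 replicate 1 and lamin A/C KO day 4 replicate 2 (adjusted p = 0.053 to 0.13), and the count was 2 without lamin A/C KO day 3 replicate 1, with the values as deposited and without the 5 arrays of a Gapdh ratio over 2. Emd (-0.04 ± 0.38 in emerin KO, -0.02 ± 0.38 in lamin A/C KO) and Lmna (0.02 ± 0.28 in emerin KO, adjusted p = 0.96 in lamin A/C KO) did not pass.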

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

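The tests of RNA quality and of mixed muscle in this part were chosen only after the results were seen, and the counts over other splits of the arrays were set before. Differences between genotypes in their response were tested themselves: 295 genes for emerin KO and 19 for lamin A/C KO against control from day 0 to day 3, and 5 and 1 from day 3 to day 4, each with its dependence on single arrays given in the report, and the responses of the 2 knockouts were not tested against each other. Signals outside the comparisons also stood out: the mean Gapdh 3'/5' ratio was 4.83 on emerin KO day 3 and 3.20 on day 4, and the dimmest Lmna probe set, not used in the comparisons, read 390 and 247 in lamin A/C KO on days 3 and 4 against 21.0 and 39.7 in control. What that probe set reads in lamin A/C KO was not tested.

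In 3 comparisons over the 3 days, only the real one of 100 splits within each day, group sizes kept, gave as many genes. Emerin KO minus control gave 2537 (highest other 1853), lamin A/C KO minus control 71 (8) and emerin KO minus lamin A/C KO 2683 (456). A chance split is an unlikely source if arrays are independent, which the labels do not say. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: 1 of 10, the real one, gave as many genes by limma from day 3 to day 4 in emerin KO (131, highest other 11) and in lamin A/C KO (228, highest other 1), and from day 0 to day 3 in lamin A/C KO (4802, highest other 0).

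Emerin KO differed from control in 1820 genes on day 3 and 655 on day 4, on arrays where a high Gapdh 3'/5' ratio goes with the group. On day 0 the Gapdh ratios (0.914 and 1.34) were near control, so the ratio as a covariate could change little. Matrix genes lower were 23 with it and 24 without, which cannot decide on RNA quality. On day 3 the covariate left the mean log2 level of these lists over 2 SE from 0: interferon response (0.95 ± 0.19 without it, 1.19 ± 0.36 with it), DNA replication (0.42 ± 0.07, 0.45 ± 0.14), matrix (-0.70 ± 0.11, -0.54 ± 0.20) and regenerating myofiber (-0.56 ± 0.09, -0.33 ± 0.15). The Gapdh ratios were 3.62 to 6.09 in emerin KO and 0.957 to 0.976 in control on that day. They do not overlap, so the covariate extends a linear slope. It cannot decide whether RNA quality is the whole cause. The slope of each gene on the ratio within the control and lamin A/C KO groups correlated at 0.331 with the day 3 effect, above all of 100 shufflings of the ratio (highest 0.318), so RNA quality may account for part of it. With the covariate the effects on single genes kept a slope of 0.534, and their median size went from 0.84 to 0.43. The median SE went from 0.21 to 0.35 and 9 genes passed, so calls ended as effects shrank and errors grew. The contractile list stood at -0.53 ± 0.15 without the covariate and -0.42 ± 0.28 with it. For these genes and lists on day 3, RNA quality and the lack of emerin cannot be told apart. A difference in background between the lines stays open, as untested.

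Regenerating myofiber genes were higher in lamin A/C KO than in control on day 0, among 84 genes that were higher. Of the 84, 14 lay over 2 SE (unadjusted) above both injected lamin A/C KO groups, more than mixed-in day 3 or 4 muscle gives. They are Atp9a, Carhsp1, Cryab, Flnc, Gstp1, Hspa1a, Hspa1b, Hspb1, Ift27, Neat1, Rab15, Sln, Sqstm1 and Uchl1, named after their values were seen. Picking the 84 on these arrays favors this. For the rest, the share of injected muscle needed had a median of 7.57% over 12 regenerating myofiber genes (quartiles 4.51 to 13.2), 2.57% over 30 macrophage genes (0.908 to 8.08), 1.91% over 31 mitosis genes (-3.26 to 5.91) and -0.371% over 25 DNA replication genes (-6.71 to 2.42). At a share of 4.51%, the mean log2 level of the cell cycle lists lay -2.28 to -0.608 SE (at 7.57%, -4.25 to -1.29) from the predicted level over 2 lists and 2 days of injected muscle, so such a mixture and an effect of the lack of lamin A/C cannot be told apart. Regeneration, handling and early injected muscle stay open, as untested: these arrays are described as 0 days after injection, the control ones as not injected.

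Myh7, Myl2 and Myl3 were lower in lamin A/C KO than in control on day 4. Uninjured muscle left in the control day 4 samples would need a median share of 5.35% for these 3 genes, and 2.03% (quartiles 0.778 to 5.03) for the 48 other genes that had fallen 8-fold or more by day 3. The shares overlap, so uninjured muscle and an earlier return of slow fiber genes in control cannot be told apart. Which part of the muscle was sampled was not tested.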

How the results depend on the processing

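The Gapdh ratio as a covariate, leaving out the 5 arrays with a ratio over 2 and shuffling the replicate numbers were chosen after the data were seen, the other settings before. Where 1 array is left in a group, it is assumed to vary like the other groups. Leaving out 1 array in turn gave counts of 1 to 10 for control day 4 minus day 3, 74 to 168 for emerin KO day 4 minus day 3, 56 to 177 for lamin A/C KO day 4 minus day 3, 159 to 563 for emerin KO minus control on day 0, 781 to 2015 for emerin KO minus control on day 3, 76 to 1225 for emerin KO minus control on day 4, 48 to 70 for lamin A/C KO minus control on day 0, 1 to 7 for lamin A/C KO minus control on day 3, 21 to 66 for lamin A/C KO minus control over the 3 days, 57 to 581 for the emerin KO interaction to day 3, 6 to 17 for the lamin A/C KO interaction to day 3, 0 to 9 for the emerin KO interaction to day 4, 0 to 2 for the lamin A/C KO interaction to day 4. The other 7 counts stayed within 1.5 times. With quantile normalization the counts moved to 8 for the emerin KO interaction to day 4. Counts with median scaling were 1 for control day 4 minus day 3, 79 for emerin KO day 4 minus day 3, 134 for lamin A/C KO day 4 minus day 3, 377 for emerin KO minus control on day 4, 50 for lamin A/C KO minus control on day 0, 20 for lamin A/C KO minus control over the 3 days, 139 for the emerin KO interaction to day 3, 8 for the lamin A/C KO interaction to day 3, 0 for the emerin KO interaction to day 4. With the values as deposited the counts moved to 356 for lamin A/C KO day 4 minus day 3, 10 for lamin A/C KO minus control on day 3, 8 for the emerin KO interaction to day 4, 2 for the lamin A/C KO interaction to day 4. Counts with the mean of all probe sets were 1 for lamin A/C KO minus control on day 3. With no intensity trend the counts moved to 1 for control day 4 minus day 3, 137 for lamin A/C KO day 4 minus day 3, 1 for lamin A/C KO minus control on day 3, 42 for lamin A/C KO minus control over the 3 days, 169 for the emerin KO interaction to day 3, 9 for the lamin A/C KO interaction to day 3, 0 for the emerin KO interaction to day 4, 0 for the lamin A/C KO interaction to day 4. Counts with a replicate block were 1 for lamin A/C KO minus control on day 3, 9 for the emerin KO interaction to day 4. With the Gapdh ratio as a covariate the counts moved to 14 for control day 4 minus day 3, 2809 for emerin KO day 3 minus day 0, 53 for lamin A/C KO day 4 minus day 3, 9 for emerin KO minus control on day 3, 20 for emerin KO minus control on day 4, 108 for emerin KO minus control over the 3 days, 153 for emerin KO minus lamin A/C KO, 16 for the emerin KO interaction to day 3, 9 for the emerin KO interaction to day 4. Counts with only the compared groups in the fit were 1 for control day 4 minus day 3, 42 for emerin KO day 4 minus day 3, 380 for lamin A/C KO day 4 minus day 3, 6 for emerin KO minus control on day 0, 1197 for emerin KO minus control on day 3, 182 for emerin KO minus control on day 4, 36 for lamin A/C KO minus control on day 0, 1 for lamin A/C KO minus control on day 3, 110 for lamin A/C KO minus control over the 3 days, 68 for the emerin KO interaction to day 3, 1 for the emerin KO interaction to day 4, 0 for the lamin A/C KO interaction to day 4. With the 5 high-ratio arrays left out the counts moved to 23 for emerin KO minus control on day 4, 2 for the lamin A/C KO interaction to day 4. Tmem38a turned with the Gapdh ratio as a covariate in emerin KO minus control on day 3 (0.79) and over the 3 days (0.16). Directions turned without control day 3 replicate 2 in lamin A/C KO minus control on day 3 for the list of glycolysis and glycogen (median 0.020, against -0.48 without replicate 1). Replicate numbers were not taken as pairs, since 26 of 82 pairs of arrays with the same number had a correlation of residuals over 0.1 (mean 0.041, -0.30 to 0.39). Their mean was reached in 2 of 100 shufflings of the numbers, so a weak tie is seen, and 11 of 23 arrays fitted best with their own number, reached in 21 shufflings. The covariance of the knockout effects was 0.0118 with split controls. The cause of these moves was not tested, except that leaving out arrays or groups lowers the number of arrays. Arrays limit small changes, as the recovered shares of simulated changes show.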

Other observations

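The day 4 test in this part was chosen only after the results were seen, and the day 3 test before. A hypothesis was that emerin KO muscle lags behind control. On day 3, over 531 genes with an unadjusted p under 0.05 from day 3 to day 4 in control, that change correlated at 0.323 with emerin KO minus control, where a lag predicts a value below 0 and a value above 0 had been set to speak against it. That bound was wrong: 558 genes are expected by chance at that p, and the control day 3 arrays shared by both differences push the correlation above 0, so the test decides nothing. On day 4, the emerin KO array of the lowest Gapdh 3'/5' ratio (1.40) differed from control with a correlation of -0.689 to the change from day 3 to day 4 in lamin A/C KO (228 genes). A lag in emerin KO is a candidate explanation, from 1 array, and the Gapdh ratio also differs between the lamin A/C KO arrays of the 2 days, so RNA quality could give the same sign.

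The median over all genes moved with median scaling from 0.08 to -0.02 in control from day 0 to day 3, from 0.09 to -0.03 for emerin KO minus control on day 0, from -0.04 to 0.07 for lamin A/C KO minus control on day 3, from -0.12 to 0.06 for the emerin KO interaction and from -0.08 to 0.10 for the lamin A/C KO interaction.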
